A study of Mus musculus with 2 samples.

How the data were processed

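H3K9ac ChIP-seq was carried out on stomachs of mouse embryos at embryonic day 15.5, in 2 biological replicates that pooled 78 and 62 embryos, as the labels state. The 4 deposited peak lists are in narrowPeak format on the mouse build mm10. Per the notes deposited with the samples, peaks were derived from alignments of the ChIP and of a control, for each replicate and for the reads of both replicates together, and the replicated list was derived from the pooled list and both replicate lists. The rule for a replicated peak, the aligner, the peak caller and its thresholds are not given in the sources used here. The deposited signal value of each peak is the authors' enrichment, how it was scaled is not stated, and it was used only within a list. The deposited significance values are −log10 of the p-value and of the q-value, and the lists reach down to a −log10 p of about 2. A summit position per peak was also deposited. Because the lists hold peaks above the authors' cutoff and no read counts, the depth per library is unknown, a promoter without a peak is one not detected in that list, and no interval that needs a depth is given.

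Chromosome names and lengths of the lists fit the reference genome GRCm38, the same build as mm10, and genes came from the GENCODE annotation of that build. Coordinates are given on mm10, counted from 1. Peaks on the 19 autosomes, X and Y were used, and the few on unplaced contigs were left out of the tests. A promoter was the 1000 bp on either side of a TSS of any protein-coding transcript, and a gene was called marked when at least 1 bp of a replicated peak touched it. For genomic location, TSSs of all annotated transcripts were used, and each peak was put into the first of promoter, exon, intron and between genes that it overlapped. A promoter was called CpG-rich when the observed to expected CpG ratio within 500 bp of a TSS was at least 0.6 at the gene's TSS with the highest ratio. Where peaks or genes are compared with chance, peak lists were placed 100 times at random on the same chromosomes outside assembly gaps, and gene lists were drawn 10000 times at random.

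With 1 group there was no contrast between conditions. The comparisons, the 25 gene lists and the alternatives were fixed before the data were examined. Lists with fewer than 5 genes (or, for breadth, fewer than 5 marked genes) were described and not tested, which left 24 lists for promoter share and distal peaks, 11 for breadth in the replicated list, and 20 and 10 for the shares among CpG-poor and CpG-rich promoters. Shares of marked genes were tested by Fisher's exact test, breadth and distal peaks against random lists by two-sided permutation, and p-values were adjusted over the lists by the Benjamini-Hochberg method with a threshold of 0.05. Of the 316 genes fixed by symbol, 1 (Ahsp) had no match in the annotation, and Cblif was matched through the older symbol Gif. Named genes were, for each list, the 3 marked members with the greatest breadth, up to 3 unmarked members in alphabetical order (for lists of other tissues, only up to 3 marked members), 17 regulators fixed by name, the 10 genes with the greatest breadth, the 10 with the highest enrichment and the 5 with the most distal peaks. Genes outside this rule are said to have been named after their values were seen, except members of lists given in full.

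Alternatives changed the overlap needed, the significance cutoff, the promoter window, the TSS used, the list (pooled, or each replicate alone), the background genes and the random lists. Leaving out a replicate meant using the list of the other replicate alone. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and bedtools 2.31.1. Overlap counts were checked with bedtools, which gave the same 17423 and 20944 peaks. The tests were tried on simulated data. For the share of marked promoters, simulated over 21853 genes with lists of 15, planted high and low shares were called in 95.8% and 94.0% of lists and unplanted ones in 0.9%. Planted shares lay far above or far below the background, so these rates do not cover smaller differences. Unplanted genes were marked at random without regard to CpG content, so the rates do not cover lists skewed in CpG content either. For breadth, simulated over 12000 genes, planted lists, all of the same effect size, were called in 77.5% and unplanted ones in 0.0%.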

Results

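Acetylation of lysine 9 of histone H3 (H3K9ac), a chromatin mark of active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the stomach of mouse embryos at embryonic day 15.5. The design held 1 group of 2 biological replicates and no second condition. Replicate 1 was a pool of stomachs from 78 embryos and replicate 2 a pool from 62 embryos of the strain B6NCrl, of mixed sex. Peaks had been called in each replicate and on the reads of both replicates together (the pooled list), and another list held the pooled peaks classed as replicated. The replicate 1 list held 39938 peaks covering 21.5 Mb, with a median width of 328 bp. The replicate 2 list held 32731 peaks covering 13 Mb, with a median width of 269 bp. The pooled list held 38613 peaks and the replicated list 20404 peaks, which covered 17 Mb with a median width of 712 bp. The enrichment of each peak is the authors' own value and is used here only to describe and rank peaks within a list. The files give no read counts, so the depth of each library is unknown. The comparisons below ask how far the replicates share peaks, where in the genome H3K9ac lies, and which cell types' genes carry it.

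Strong peaks, which lay at promoters, were found in both replicates, and weak peaks away from promoters mostly in only 1 of them. Of the 39931 replicate 1 peaks on chromosomes, 17423 (43.6%) were overlapped by at least 1 bp of a replicate 2 peak. Of the 32717 replicate 2 peaks, 20944 (64.0%) were overlapped by a replicate 1 peak. Placing the other list at random gave means of 1.34% and 1.63%, so the observed shares were 32.7-fold and 39.3-fold higher (one-sided permutation p = 0.0099 for each, the smallest that 100 placements can give). Random placement ignored promoters, where most peaks of both lists lay, so this excess includes what a shared location at promoters alone would give. Peaks within 1 kb of an annotated transcription start site (TSS) were shared at 63.5% in replicate 1 and 89.9% in replicate 2. Peaks farther away were shared at 11.0% and 18.1%. In the strongest decile of each list's own p-values, 99.9% of replicate 1 peaks and 100% of replicate 2 peaks had a partner, against 6.33% and 25.7% in the weakest decile. The replicate 2 list was weaker by its own values. Its highest −log10 q was 39.3 against 85.7 in replicate 1, and 74.5% of its peaks against 84.2% had a q-value under 0.05.

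**Figure D1:**
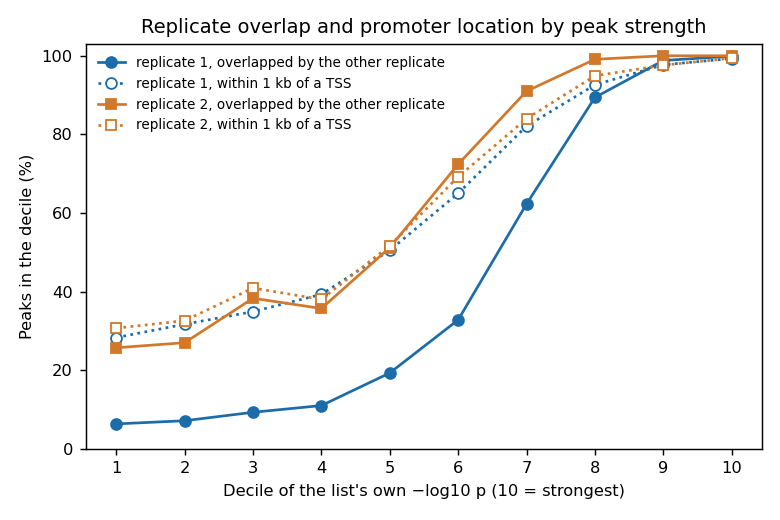
Share of peaks (%, vertical axis) overlapped by a peak of the other replicate (solid lines) and lying within 1 kb of a TSS (dotted lines), by decile of the list's own −log10 p (horizontal axis, 10 is the strongest), for replicate 1 (blue circles) and replicate 2 (orange squares). Overlap runs from 6.33% to 99.9% in replicate 1 and from 25.7% to 100% in replicate 2.

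The replicated list was a subset of the pooled list, and held its wide and enriched peaks. All 20404 replicated peaks were pooled peaks, 52.8% of that list. Their median enrichment was 5.21, against 2.60 in the 18209 pooled peaks that were not in the replicated list, and their median width was 712 bp against 216 bp. Of the replicated peaks, 16826 (82.5%) met a peak of each replicate with an overlap of at least 50% of either peak. The remaining 3578 did not, and 3301 replicated peaks had no overlap at all with a replicate 2 peak, against 294 with none in replicate 1. The replicated list therefore holds peaks seen in the list of 1 replicate only, and 79 of its peaks had a q-value above 0.05.

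H3K9ac was concentrated at promoters. Of the 20398 replicated peaks on chromosomes, 17790 (87.2%) touched the 1 kb on either side of an annotated TSS, 9.95-fold more than the 8.76% ± 0.24 (SD, 100 placements) of peaks placed at random. Exons away from promoters held 2.60% of the peaks (random 7.43%), introns 5.35% (random 35.2%) and the space between genes 4.83% (random 48.6%). All 4 shares differed from random placement (two-sided permutation p = 0.0198 for each, the smallest possible here). The promoter share was 62.1% in the list of replicate 1 alone and 63.9% in that of replicate 2 alone.

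Promoters of 12471 of 21853 protein-coding genes (57.1%) carried a replicated peak. The list of replicate 1 marked 13332 genes and that of replicate 2 marked 12363, with 12078 genes in both. CpG-rich promoters carried H3K9ac in 10347 of 11238 genes (92.1%), and CpG-poor promoters in 2124 of 10615 (20.0%), an odds ratio of 46.4. The two-sided p of Fisher's exact test was below the smallest number the software can hold. The 10 promoters with the highest enrichment were led by Wtap, a subunit of the complex that methylates adenosines in RNA (enrichment 19.6 in the replicated list, 21.3 in replicate 1 and 12.2 in replicate 2), and Sp3, a zinc finger transcription factor (18.97, 21.5 and 10.3). Next were Msl1, Nrf1, Dctn2, Prrc2a, the ribosomal protein gene Rps19, Cnot3, the translation initiation factor gene Eif3a and Atxn2l, down to 16.3. At Wtap the peak lay at 12990812 to 12992582 on chromosome 17, and at Sp3 at 72979422 to 72980429 on chromosome 2 (mm10).

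Breadth was the length covered by replicated peaks within 5 kb of a TSS, including peaks at neighbouring genes. A gene with several TSSs was given its greatest value. Breadth had a median of 1305 bp (quartiles 869 and 1851 bp) over the marked genes. The greatest breadth was 9158 bp at Tnrc18. It was followed by the homeobox gene Meis2 (8876 bp), the forkhead gene Foxf1 (8124 bp), the nuclear receptor gene Nr2f2 (7567 bp) and the homeobox gene Meis1 (7312 bp). Irf2bp2 (7173 bp), Pitx1 (6641 bp), the histone methyltransferase gene Setd1b (6628 bp), Hoxa2 (6625 bp) and Bcl11a (6596 bp) completed the 10 broadest. None of these was among the 10 most enriched, although Setd1b reached an enrichment of 13.1.

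Regulators of gut mesenchyme carried H3K9ac at 23 of 24 promoters (95.8%), against 57.0% of other genes (Fisher's exact test, two-sided, adjusted p = 0.000168 over 24 fixed lists). All 24 were marked in replicate 1 and 21 in replicate 2. At Barx1, a homeobox factor of the stomach mesenchyme (chromosome 13, 48662998 to 48666507), a single peak from 48662988 to 48666947 spanned the whole gene, with an enrichment of 7.40 (8.003 in replicate 1, 5.22 in replicate 2). At Foxf1, a target of hedgehog signalling in gut mesenchyme, the strongest promoter peak lay just upstream of the gene, at 121080165 to 121084062 on chromosome 8, with an enrichment of 6.62 (8.19 and 6.27). The strongest promoter peak of Meis2 lay inside the 5′ end of the gene, at 116060154 to 116064983 on chromosome 2. Weaker members were Nkx2-5, a homeobox factor of the pyloric region, with 286 bp and an enrichment of 2.62, and Nkx3-2, with 886 bp and a peak in replicate 1 but not in replicate 2. The unmarked member was Nkx2-3, which had a promoter peak in replicate 1 alone (enrichment 3.09).

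Regulators of the gastric epithelium were marked at 11 of 15 promoters (73.3%), which did not differ from other genes in the replicated list (57.1%, Fisher's exact test, adjusted p = 0.34). The call changed with the list. All 15 were marked in replicate 1 (adjusted p = 0.00215), 13 of 15 in replicate 2 (adjusted p = 0.0324) and 15 of 15 in the pooled list (adjusted p = 0.00233), by the same exact test. The marked members included Klf4 (4080 bp, enrichment 5.20), Gata6 (3222 bp, 4.54), Hnf1b (3069 bp, 4.63), Gata4 (2851 bp, 5.12), Foxa2 (1857 bp, 4.31) and Sox2 (1521 bp, 5.55). Sox2 is a transcription factor of foregut epithelium, and its peak lay at 34650108 to 34650943 on chromosome 3, across the start of the gene. Hnf4a, a nuclear receptor of gut epithelium, and Ehf had weak promoter peaks in both replicate lists but none in the replicated list. For Hnf4a their enrichment was 2.67 in replicate 1 and 2.99 in replicate 2. Esrrg had a peak in replicate 1 alone.

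Genes of simple epithelium were marked at 9 of 18 promoters (exact test, adjusted p = 0.664). With peaks of a −log10 q of at least 10 alone, 3 of 18 were marked, fewer than the 47.5% of other genes (adjusted exact p = 0.0125). The marked members included the hedgehog ligands Ihh (2001 bp, enrichment 4.10) and Shh (1794 bp, 2.68) and the keratin gene Krt8 (1504 bp, 3.93). Of the named members without a replicated peak, Anxa10 and the protease gene Ctse had no promoter peak in either replicate, and the claudin gene Cldn18 had one in replicate 1 alone. None of 18 genes for products of the mature gastric glands was marked (adjusted exact p = 2.92e-06). They included Atp4a and Atp4b, the subunits of the proton pump of parietal cells, with no promoter peak in either replicate, and Bhlha15, a transcription factor of secretory cells, with weak peaks in both replicate lists (enrichment 2.67 and 3.48). Genes of the squamous forestomach were marked at 1 of 11 promoters, Irf6 (adjusted exact p = 0.00263). Trp63, the regulator of squamous epithelium, had a peak in replicate 1 alone (enrichment 2.91), and Dsg3, Krt13 and Krt14 had none. In the lists of replicate 1 and of the pooled reads, 45.5% of the squamous genes were marked, which did not pass the test (adjusted exact p = 0.43 and 0.42). Most genes of both lists have CpG-poor promoters, where 20.0% of other genes were marked. Of the mature gastric products 0 of 17 such promoters were marked, the lowest value possible, with an unadjusted exact p of 0.0333 and an adjusted p of 0.111. The 10 CpG-poor squamous genes, 1 of them marked, were too few to pass even with none marked (unadjusted exact p = 0.228).

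Smooth muscle genes were marked at 13 of 17 promoters (76.5%) and fibroblast and matrix genes at 11 of 14 (78.6%), neither of which passed the test in the replicated list (Fisher's exact test, adjusted p = 0.189 and 0.221). Both passed in replicate 1 alone, with 17 of 17 (adjusted exact p = 0.000791) and 13 of 14 (adjusted p = 0.0206). The pooled list gave the same counts (adjusted exact p = 0.00184 and 0.0228). Neither passed in replicate 2 alone, with 11 of 17 and 10 of 14 (adjusted exact p = 0.654 and 0.373). Most of these promoters were CpG-poor. Among CpG-poor promoters, 10 of 14 smooth muscle genes (71.4%, adjusted p = 0.000456) and 6 of 9 fibroblast genes (66.7%, exact test, adjusted p = 0.0153) were marked, against about 20.0% of other genes. The other genes were not matched on CpG ratio within this class. Ratios of the smooth muscle genes in it ran from 0.19 at Actg2, unmarked, to 0.58 at Tpm2, marked. A remaining effect of CpG content is therefore not excluded. The broadest were the tropomyosin genes Tpm1 (4157 bp, enrichment 8.22) and Tpm2 (2726 bp, 4.35) and the myosin light chain gene Myl9 (2536 bp, 5.40). Among matrix genes these were Col5a1 (2801 bp, 8.73), Col1a1 (2663 bp, 5.71) and Sparc (2172 bp, 4.25). The contractile genes Actg2, Cnn1 and Lmod1 and the matrix genes Dcn and Postn had promoter peaks in replicate 1 alone, and Lum had none.

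Markers of other cell types of the stomach wall were marked less evenly. The samples were pools of stomachs, so a peak cannot be assigned to a cell type. The share of each cell type was not measured, so few marked genes cannot be told from few cells of that type. Enteric neural genes carried a peak at 5 of 16 promoters (31.2%, adjusted exact p = 0.0626). Hand2 (3762 bp, enrichment 7.03), Erbb3 (1521 bp, 6.79) and Ednrb (1263 bp, 4.29) were marked. Sox10 and Phox2b, transcription factors of neural crest derivatives, had no promoter peak in either replicate, and Ret, a receptor of enteric neural precursors, had one in replicate 2 alone. Among CpG-rich promoters the enteric neural share, 5 of 11 (45.5%), was below the 92.1% of other genes (adjusted exact p = 0.000266). With peaks of a −log10 q of at least 10 alone, enteric neural genes (2 of 16, adjusted exact p = 0.00907) and endothelial genes (1 of 14, adjusted p = 0.00523) were lower than other genes (47.5%). All 3 genes of interstitial cells of Cajal, the pacemaker cells of the gut, were marked (Kit, Ano1 and Etv1), too few for a test. Mesothelial genes were marked at 5 of 8 promoters (exact test, adjusted p = 1.0) and endothelial genes at 6 of 14 (adjusted p = 0.34), among them the receptor gene Kdr (697 bp, enrichment 4.94). Erythroid genes were marked at 2 of 15 (adjusted exact p = 0.00172), namely Klf1 (1634 bp, enrichment 8.64), a red cell transcription factor, and Nfe2. Immune genes were marked at 1 of 15, Aif1 (adjusted exact p = 0.000259). In replicate 1 alone 5 of 15 erythroid genes (33.3%, adjusted exact p = 0.0486) and 3 of 15 immune genes (adjusted p = 0.00394) were marked. Among CpG-poor promoters the shares were 14.3% and 6.67%, against 20.0% of other genes, in lists too small to pass the test even with none marked (unadjusted exact p = 0.0876 and 0.0531).

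Genes of other tissues were rarely marked. The share was lower than in other genes for intestine (1 of 12, adjusted exact p = 0.00145), pancreas (2 of 13, adjusted p = 0.00528), liver (1 of 13, adjusted p = 0.00092), skeletal muscle (0 of 13, adjusted p = 0.000101), forebrain (1 of 17, adjusted p = 0.000101) and germline (1 of 10, adjusted p = 0.0052). Heart (0 of 9, adjusted p = 0.00127) was lower by the same exact test and lung (2 of 9, adjusted p = 0.0626) did not pass it. Lung passed in replicate 1 alone (adjusted exact p = 0.0486), in the pooled list (0.0457), in windows not shared with another gene (0.0477) and at a −log10 q of at least 10 (0.0495). None of 1134 olfactory receptor genes was marked in the replicated list. The marked exceptions included Pdx1, a homeobox factor of pancreas, duodenum and distal stomach (451 bp, enrichment 3.33, chromosome 5, 147270244 to 147270694), the endocrine factor gene Nkx6-1 (1555 bp, 4.63), Satb2 (1501 bp, 6.94), Hnf1a (2043 bp, 4.86) and Dazl (641 bp, 4.17). Cdx2, the regulator of intestinal identity, and Nkx2-1, that of lung and thyroid, had no promoter peak in either replicate. Most of these lists held mainly CpG-poor promoters. Among CpG-poor promoters the olfactory receptors were lower than other genes (0 of 1133, adjusted exact p = 3.55e-116). The intestine, pancreas, liver, heart, skeletal muscle and germline calls were lost there (adjusted exact p between 0.389 and 0.735), but those lists were too small to pass, since even with none marked their unadjusted p would be 0.0848 or more. Forebrain genes were mainly CpG-rich and were marked at 1 of 13 such promoters (7.69% against 92.2%, adjusted exact p = 6.95e-12). The intestine call was lost in the list of replicate 2 alone (adjusted exact p = 0.062). The pancreas call was lost in replicate 2 alone (adjusted exact p = 0.13), in replicate 1 alone (5 of 13, adjusted p = 0.202) and in the pooled list (5 of 13, adjusted p = 0.126). All 17 housekeeping genes (adjusted exact p = 0.000292) and all 14 cell cycle genes (adjusted p = 0.00127) were marked, among them Actb, Gapdh, Tubb5, Plk1, Aurka and Mcm2. Among CpG-rich promoters alone their share and that of the mesenchyme regulators were 100% against 92.1% of other genes, a base so high that lists of 12 to 18 genes cannot pass the test. Among CpG-poor promoters 5 of 6 mesenchyme regulators (83.3%) were marked, against 20.0% of other genes (adjusted exact p = 0.0107). Their CpG ratios ran from 0.44 to 0.59, below the cut of 0.6, and the other genes were not matched on the ratio. The test therefore does not fully separate these regulators from the CpG content of their promoters. The genes are the units of these tests, and genes that share a promoter window (3169 of those annotated) are not independent.

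**Figure D2:**
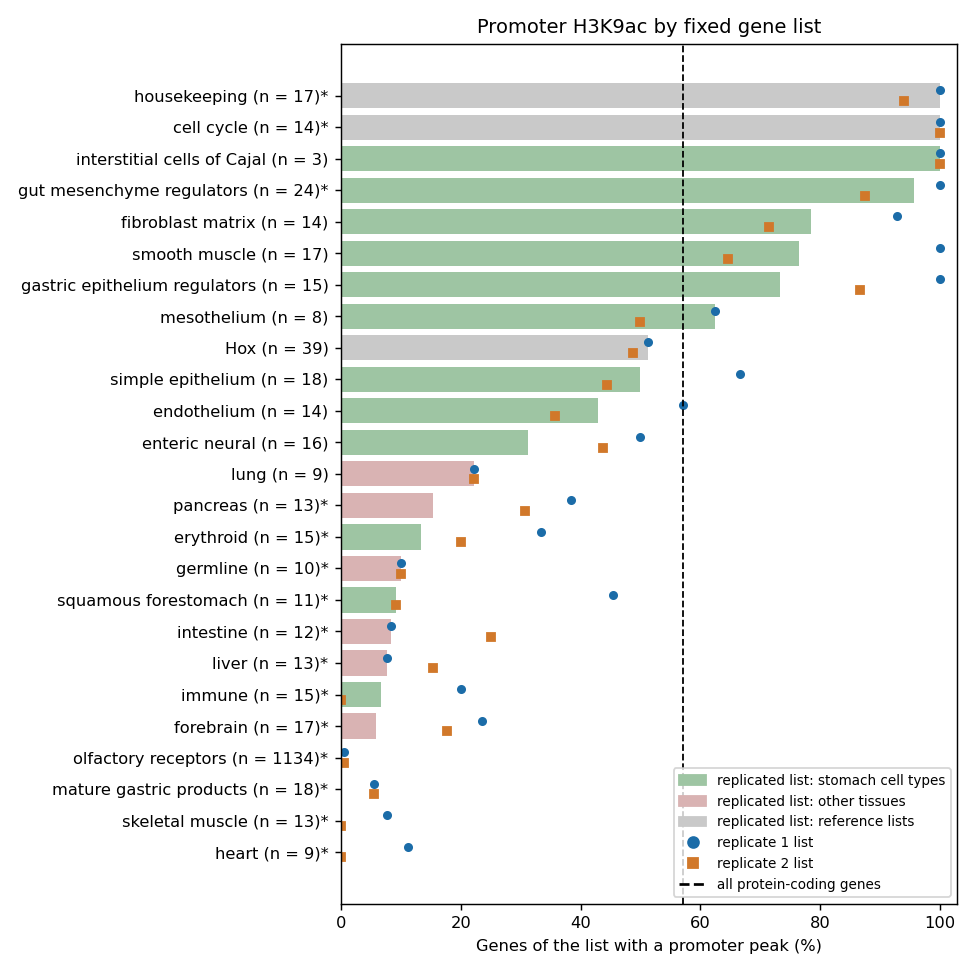
Share of the genes of each fixed list with a promoter peak (%, horizontal axis) in the replicated list (bars, green for cell types of the stomach, red for other tissues, grey for reference lists), in replicate 1 (blue circles) and in replicate 2 (orange squares), with the number of genes per list and an asterisk where the adjusted p was under 0.05. The dashed line marks the 57.1% of all protein-coding genes, and gut mesenchyme regulators stand at 95.8%.

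Marked promoters of mesenchyme regulators were broad. The median breadth was 2649 bp over 23 mesenchyme regulators, 2454 bp over 20 Hox genes, 2369 bp over 17 housekeeping genes, 2238 bp over 11 gastric epithelium regulators and 2083 bp over 11 fibroblast genes. The windows of neighbouring Hox genes overlap, so the Hox value includes peaks at adjacent Hox promoters and is not the breadth of single promoters. Random lists of marked genes had medians of about 1300 bp (two-sided permutation, adjusted p = 0.0011, 0.0011, 0.0015, 0.0093 and 0.0255). The random lists were not matched on the number of TSSs per gene, and more TSSs give more windows from which the greatest value is taken. Endothelial promoters were narrow, with a median of 669 bp over 6 genes (permutation, adjusted p = 0.0323). Smooth muscle (1428 bp), simple epithelium (1491 bp), cell cycle (1514 bp) and enteric neural genes (1263 bp) did not differ from random lists, and mesothelium (639 bp) missed the threshold (permutation, adjusted p = 0.0585 over 5 genes). Mesothelium passed as narrow with the 10 kb window (permutation, adjusted p = 0.0491), in replicate 1 alone (0.0253) and against random lists matched on CpG ratio (0.022). In the pooled list enteric neural genes passed as narrow, with a median of 722.5 bp over 8 genes against 1392 bp (permutation, adjusted p = 0.0489). Lists with enough marked genes only in other peak lists also passed as narrow, namely erythroid (permutation, adjusted p = 0.039) and pancreas genes (0.0155) in replicate 1 alone and olfactory receptors in replicate 1 (0.001) and replicate 2 alone (0.0066). In replicate 2 alone, only the mesenchyme regulators were broader than random lists. The fibroblast call was also lost in replicate 1 alone (permutation, adjusted p = 0.126), in the pooled list (0.0657) and with windows of 2 kb (0.139) and 10 kb (0.0927). With the 2 kb window the gastric epithelium (permutation, adjusted p = 0.3109), Hox (0.4013) and endothelial (0.0843) calls were lost too. The endothelial call was lost as well in replicate 2 alone (permutation, adjusted p = 0.0566), in the pooled list (0.1461) and against random lists matched on CpG ratio (0.1768). Ranked by the enrichment of the strongest promoter peak, no list was higher than random lists and 5 were lower. These were Hox genes (median percentile 38.5), mesothelium (10.98) and endothelium (23.5, permutation, adjusted p = 0.0044 for each), simple epithelium (34.6, adjusted p = 0.017) and smooth muscle (42.4, adjusted p = 0.0251).

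Distal H3K9ac lay near mesenchyme regulators more often than near other genes. There were 2608 replicated peaks (12.8%) that touched no promoter window, and a gene had a mean of 0.351 of them in its body and 50 kb on either side. Mesenchyme regulators had a mean of 1.83, against 0.351 in random lists matched on gene length, and 21 of the 24 had at least 1 (two-sided permutation, adjusted p = 0.0016). Foxf1 had 6, Meis2 had 5 and Barx1 had 3. The window of Foxf1 meets that of another member of the list, so peaks there can count for both. Distal peaks within 5 kb of a TSS can also count towards breadth, so the 2 results are not independent. Random lists were not matched on whether the promoter was marked. With distal peaks restricted to a −log10 q of at least 10, few peaks were left and the call was lost, with a mean of 0.292 against 0.0588 in random lists (permutation, p = 0.0216, adjusted p = 0.1296). Hox genes had a mean of 4.90 against 0.376 (permutation, adjusted p = 0.0016), but the windows of neighbouring Hox genes overlap, so the same peaks count for several genes. Olfactory receptor genes had a mean of 0.0309 against 0.374 (permutation, adjusted p = 0.0016). Gastric epithelium regulators had a mean of 1.07 against 0.342 (permutation, adjusted p = 0.1076), and with 20 kb on either side they passed the test (1.07 against 0.196, permutation, adjusted p = 0.0192). In replicate 1 alone smooth muscle genes (permutation, adjusted p = 0.0317) and cell cycle genes (0.0264) passed too. Housekeeping genes passed in the pooled list (permutation, adjusted p = 0.0288) and against lists not matched on length (0.042). The highest counts were 26 at Gm20388, a gene model that spans 119910841 to 124345722 on chromosome 8, and 16 each at Hoxb3, Hoxb4, Hoxb5 and Hoxb6.

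Hox genes, which record position along the body axis, were marked at the 3′ side of their clusters and not at the 5′ side. As a list, 20 of 39 were marked (adjusted exact p = 0.566), and 10 of 39 at a −log10 q of at least 10, fewer than other genes (adjusted p = 0.0106). The overall share hides opposite calls by CpG class. CpG-poor Hox promoters were marked in 6 of 11 genes, more than the 20.0% of other genes (adjusted exact p = 0.0466), and CpG-rich ones in 14 of 28, fewer than the 92.2% of other genes (adjusted p = 2.46e-08). Promoters of paralog groups 1 to 5 were marked in 12 of 15 genes (80.0%) and those of groups 6 to 13 in 8 of 24 (33.3%, Fisher's exact test, two-sided, p = 0.00791). With the line drawn after group 8, an alternative fixed with the others, 20 of 23 genes and 0 of 16 were marked (p = 2.57e-08 by the same exact test). The unmarked genes of the low groups were Hoxb1, Hoxd1 and Hoxd4, named after their values were seen. The broadest were Hoxa2 (6625 bp), Hoxb3 (5593 bp) and Hoxb4 (4950 bp). Hoxa11 and Hoxa13 had no promoter peak in either replicate, and Hoxa10 had one in replicate 2 alone (enrichment 2.77). Neighbouring Hox genes share regulation, so the test counts as separate 39 genes that lie in 4 clusters.

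**Figure D3:**
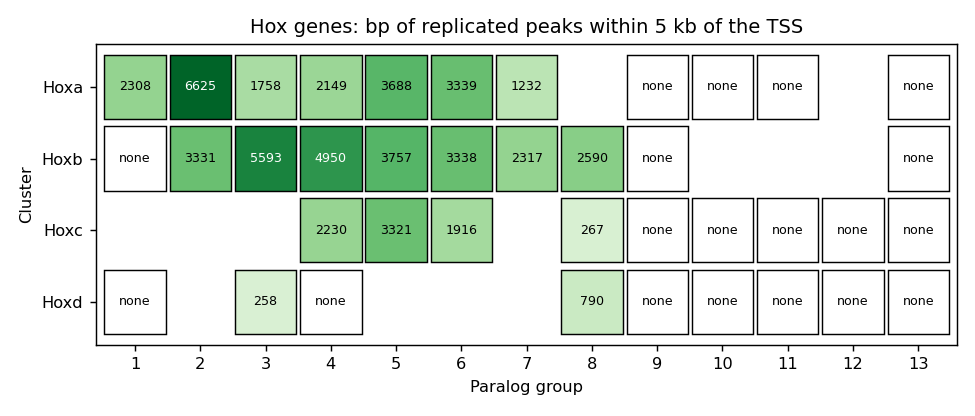
Length covered by replicated peaks within 5 kb of the TSS (bp, number and green shade) for the 39 Hox genes, by cluster (rows) and paralog group (columns); "none" marks a gene without a replicated promoter peak, and empty places hold no gene. Marked genes lie in groups 1 to 8, and the 16 genes of groups 9 to 13 are without a replicated promoter peak. Of these, Hoxa9 is shown as "none" but has 553 bp of replicated peaks within 5 kb.

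**Figure D4:**
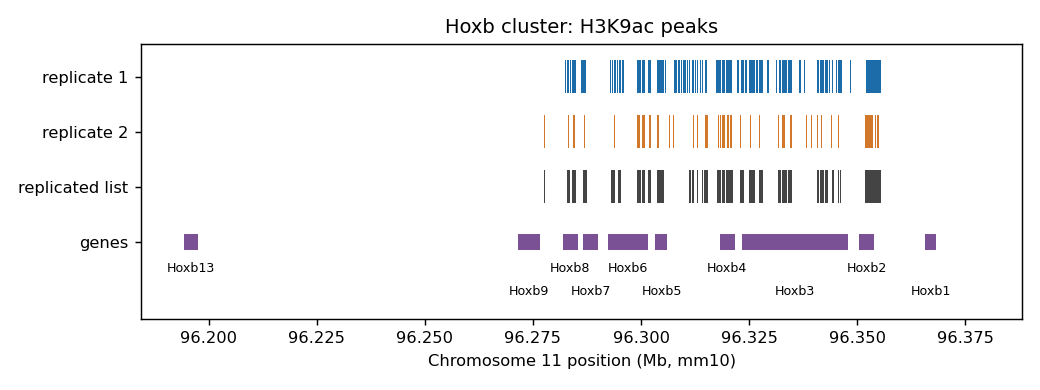
Map of the Hoxb cluster on chromosome 11 (Mb, mm10, horizontal axis) with the peaks of replicate 1 (blue), replicate 2 (orange) and the replicated list (dark grey) above the gene spans (purple). Peaks run from beside Hoxb9 to Hoxb2, and neither Hoxb13 nor Hoxb1 carries one.

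The replicates differed in which weak promoters were called. A promoter peak was present in replicate 1 alone for 1254 genes and in replicate 2 alone for 285, while 8236 genes had none in either. Of the smooth muscle genes, 6 were called in replicate 1 alone, namely Acta2, Actg2, Cnn1, Lmod1, Myh11 and Mylk, all structural or regulatory parts of the contractile apparatus (Acta2, Myh11 and Mylk were named after their values were seen). In replicate 1 alone there were also 4 genes each of simple epithelium and squamous forestomach and 3 each of mesenchyme regulators, fibroblast, endothelial, immune and forebrain genes. In replicate 2 alone there were 2 intestinal and 2 forebrain genes. With 1 library on each side, these differences have no test.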

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

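The replicated list held 6 peaks on unplaced or unlocalised contigs, which the comparisons left out. They are given because the number is above the 3 that a count of 0 allows, a low bar with no control to set beside it. The pooled list had 13 such peaks, replicate 1 had 7 and replicate 2 had 14. No gene was assigned to them.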

How the results depend on the processing

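Replicate overlap, genomic location, the CpG contrast and the Hox contrast kept their direction and their side of the threshold under every alternative run for them, which for the last 3 included each replicate alone. Counts of marked genes, which have no test, stayed within 1.5 times of 12471. Overlap ran from 32.5% to 55.5% of replicate 1 peaks and from 61.3% to 99.2% of replicate 2 peaks. Counts of lists past the threshold moved. Lists with a higher promoter share numbered 3 and rose to 6 with the pooled list, were 4 among CpG-poor promoters and 0 among CpG-rich ones, where 92.1% of all genes are marked and no tested list could pass, and were 4 and 6 in replicate 2 and replicate 1 alone. Lists with a lower share numbered 12, were 17 at a −log10 q of at least 10, and were 1 among CpG-poor and 3 among CpG-rich promoters, where fewer genes enter the test and most CpG-poor lists were too small to pass. Lists with greater breadth numbered 5 and were 2 with a 2 kb window, 0 by percentile of enrichment, and 1 and 4 in replicate 2 and replicate 1 alone. Lists with less breadth numbered 1 and were 0 with a 2 kb window, 2 with a 10 kb window, 5 by percentile of enrichment, and 1 and 5 in the single replicates. By percentile of enrichment the medians of gastric epithelium regulators (49.0), mesenchyme regulators (58.5), fibroblast genes (56.9) and Hox genes (38.5) lay below the median of random lists, against the direction found for breadth, but of these 4 only the Hox genes differed from random lists. Lists with more distal peaks numbered 2 and were 1 at a −log10 q of at least 10, and 2 and 4 in replicate 2 and replicate 1 alone. Apart from the smaller CpG classes, the cause of these changes was not tested. Of the single-list results for promoter share, most kept their side of the threshold, some passed it newly and 19 lost it. No paired analysis was possible because the design has 1 group. Depth is unknown, so a promoter without a peak cannot be told from one under the detection limit.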

Other observations

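The gene families, the noncoding RNA genes, the X chromosome and the tests of explanations for the smooth muscle, other-tissue and Hox patterns were chosen after the main results were seen. The test of summit position was chosen after them too, but its outcome was stated before it was run. Families defined by gene symbol differed in promoter H3K9ac (Fisher's exact test, two-sided, adjusted over 20 families, replicated list). Each family was compared with all other genes and was not split by CpG class. Since 92.1% of CpG-rich and 20.0% of CpG-poor promoters were marked, these tests cannot separate a family from the CpG content of its promoters. All 78 mitochondrial ribosomal protein genes (adjusted exact p = 4.79e-19), 77 of 80 cytosolic ribosomal protein genes (adjusted p = 5.28e-15) and 45 of 46 genes named as NADH dehydrogenase subunits or their assembly factors (adjusted p = 5.83e-10) were marked. Zinc finger genes of the Zfp series were marked at 318 of 394 promoters (80.7%, adjusted exact p = 1.42e-22). Replication-dependent histone genes were marked at 55 of 67 (82.1%), with 57 in replicate 1 and 38 in replicate 2. Keratin genes were marked at 3 of 53 promoters (Krt8, Krt10 and Krt18, adjusted exact p = 5.28e-15), with 10 in replicate 1 and 3 in replicate 2, cytochrome P450 genes at 17 of 100 (adjusted p = 8.4e-16) and claudins at 10 of 33 (adjusted p = 0.00366). Keratin-associated proteins (0 of 57), defensins (0 of 64) and bitter taste receptors (0 of 35) had no marked member. Forkhead (25 of 44), Sox (13 of 19), Wnt (9 of 19), T-box (4 of 13) and collagen genes (26 of 44) did not pass the test.

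Noncoding RNA genes were seldom marked away from protein-coding promoters. Of 7967 long noncoding RNA genes with no protein-coding promoter window nearby, 397 (4.98%) carried a replicated peak, against 1498 of 2153 (69.6%) that lay beside one. The list of replicate 1 alone marked 648 of the independent genes and that of replicate 2 alone 477. The broadest of the independent genes were Gm16141 (8232 bp), 4932422M17Rik (7604 bp), Hoxaas3 (7099 bp) and Gm15050 (7004 bp). Independent means only that the 1 kb windows did not meet. Gm16141 starts at 19013817 on chromosome 11, inside the promoter peak of Meis1. Next were Malat1 (5671 bp, chromosome 19, 5795690 to 5802672) and Carmn, a long noncoding RNA of smooth muscle (5503 bp, chromosome 18, 61649625 to 61665537), both marked in each replicate. Genes on the X chromosome were marked less often than autosomal genes. The lists are cut at a threshold, so a lower share cannot be told from a weaker signal per promoter. The number of X copies in these pools of mixed sex was not taken into account. Among CpG-rich promoters 228 of 292 X-linked genes (78.1%) and 92.5% of autosomal genes were marked (Fisher's exact test, two-sided, p = 2.4e-14). Among CpG-poor promoters the shares were 14.5% and 20.7% (exact p = 7.35e-05). The CpG-rich difference was present in replicate 1 (84.2% against 94.6%) and in replicate 2 (71.2% against 91.4%).

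The 6 smooth muscle promoters with a peak in replicate 1 alone may reflect a less sensitive replicate 2 list. Of the 17 smooth muscle promoters with a peak in replicate 1, 64.7% also had one in replicate 2. Random genes matched on the −log10 p of their replicate 1 promoter peak gave a mean of 76.5% (95% of random lists between 58.8% and 94.1%, two-sided permutation p = 0.2974). Smooth muscle promoters were weak in replicate 1, with a median −log10 p of 8.97 against 20.5 over all marked genes, so this share is within what peak strength alone gives. A difference in tissue makeup between the pools stays open, and no biological explanation was tested because the design has 1 group.

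Low CpG content is a possible explanation for the few marked promoters among genes of other tissues, since most of these promoters are CpG-poor. Taken as 1 set without the olfactory receptors, 2 of 68 CpG-poor members (2.94%, exact 95% interval 0.358% to 10.2%) were marked, against 20.1% of other CpG-poor genes (Fisher's exact test, two-sided, p = 9.02e-05). Of the 28 CpG-rich members, 6 (21.4%, exact interval 8.30% to 41.0%) were marked, against 92.2% (exact p = 1.13e-19). Both values argue against the CpG class as the whole explanation. Genes were not matched on CpG ratio within a class, so smaller differences in CpG content remain. Of the 28 CpG-rich members, 13 were forebrain genes, 1 of them marked, so that value rests largely on this list. Mappability of the promoters was not tested, no biological explanation was tested, and the members were picked as tissue-restricted genes.

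The absence of marked Hox promoters after paralog group 8 could come from CpG content or from the cutoff of the replicated list. Among CpG-rich Hox promoters, 14 of 15 in groups 1 to 8 and 0 of 13 in groups 9 to 13 were marked (Fisher's exact test, two-sided, p = 7.48e-07), which argues against the first. Over all Hox promoters, CpG-rich or not, the median CpG ratio was 0.689 in groups 1 to 8 and 0.739 in groups 9 to 13. In the pooled list 20 of 23 and 0 of 16 (0.0%) were marked (exact p = 2.57e-08), which argues against the second. Neighbouring genes are not independent, and mappability and biological explanations were not tested.

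A further hypothesis was that promoter peaks have their summit downstream of the TSS, in the direction of transcription. Over 2031 genes with 1 TSS, 1 replicated promoter peak and no shared window, 1898 summits (93.5%, exact 95% interval 92.3% to 94.5%) lay downstream, at a median offset of 242 bp (quartiles 163 and 378 bp), which is consistent with the hypothesis for such simple promoters.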
